A study of Cicer arietinum with 18 samples.

How the data were processed

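RNA abundance was measured on a spotted 2-colour cDNA array in shoots of chickpea (Cicer arietinum) seedlings aged 14 days. Treated and untreated control RNA were hybridised together. The 18 samples combine 3 genotypes (FLIP94-508C, ICC3996 and Lasseter), 3 treatments and 2 harvest times, 3 h and 27 h after treatment. The treatments were salicylic acid (SA), methyl jasmonate (MeJA) and aminocyclopropane carboxylic acid (ACC).

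Per the labels, each deposited column is the authors' mean of 3 biological replications that included dye swaps. The series' design text adds 6 technical replicates and a total of 324 images from 54 slides. The values of the single replications were not used here, so no sample has an error of its own. Per the design text, the authors scanned the slides on an Affymetrix scanner with Jaguar 2.0 and quantified the spots with ImaGene 5, which the deposited readme gives as version 5.5. The authors then used GeneSight 3 to subtract the mean local background, omit flagged spots, apply Lowess normalisation, form a Cy5/Cy3 ratio, take a shifted logarithm and combine duplicate spots. The deposited values were therefore used as log2 ratios, as the authors' design text describes them. The size of the shift before the logarithm is not given in the sources used here. A shift pulls the ratios of dim spots towards 0, so fold values are on the shifted scale.

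The direction of the ratio is not stated for the deposited column. It is likely treated over control, because the labels list the control as channel 1 and the treatment as channel 2, and the design text speaks of changes relative to the untreated control. The lowest correlation between any pair of the 18 samples was -0.23, across features. Signs in the text rest on this reading.

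The value table holds 715 experimental features, and 181 was the largest number omitted in 1 sample. Their identifiers fall into 117 that start with CA, 156 that start with LS and 442 that start with U. None of the 715 identifiers matched the reference gene table used here (assembly Cicar.CDCFrontier_v2.0), and the files used here do not pair them with genes. Features are therefore reported by identifier. The 19 gene lists fixed before the data were examined could not be matched to any feature (0 lists matched), and the planned tests of list shifts were not run. The array also holds control features: 4 blank spots, 3 negative controls and 2 Cy5 spots have no values, and 3 features named NORMCON have values and were kept out of the tests.

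Features with a value in at least 2 of the 3 samples of each of the 6 groups were tested, which left 523 of 715. Of these, 444 had a value in all 18 samples. Moderated linear models were fitted with limma 3.58.1 in R 4.3.3 on the deposited values, with 6 hormone-by-time means and a genotype term, leaving 10 residual degrees of freedom. A response was the mean log2 ratio of a group over the 3 genotypes, tested against 0. The same fit gave the differences between times, hormones and genotypes. Interactions were tested with a moderated F test, that of hormone and genotype in a model with 8 residual degrees of freedom and 515 features, in which the 2 times were the repeats. All tests were two-sided, with Benjamini-Hochberg adjustment over the features tested and a threshold of 0.05. Below, "SE" is the standard error from limma, and every adjusted p of a feature is from limma.

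The genotypes served as the replicates of a treatment (n = 3). With the genotype term, p-values measure how unevenly the genotypes responded from group to group, together with measurement error, pooled over the 6 groups. The same genotype was sampled in every group, which is why the genotype term was part of the model. The 6 hormone-by-time groups shared 1 estimate of the spread, although SD over the features of a sample ran from 0.28 to 1.22 (log2). For each sample, features at least 2-fold from control were also counted, a measure chosen after seeing the data. These counts were compared by exact permutation tests over all splits and, as a paired alternative added after seeing the data, over exchanges within pairs of samples that share the other factors, both two-sided, with Benjamini-Hochberg adjustment over 7 comparisons. Arrays give no read depth. Their number and the omitted spots, 10.6% to 25.3% of the features of a sample, limit the precision.

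The rule for named features was written before the data were examined: the largest changes in each direction among features past the threshold, and for the responses with the same sign in all 3 genotypes. Because no gene names were at hand, at most 2 features in each direction are printed for a comparison. Where none passed for a hormone, the largest mean responses are given and said not to pass.

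The tests were tried on simulated data for the comparison of 27 h with 3 h under SA, with 200 of 523 features changed and the same spread in every sample. They recovered 48% of the 2-fold and 90% of the 4-fold changes, and 6 of 144 calls (4.17%) were false. The F test of the interaction of hormone and time recovered 24% and 65% of the same changes. Because the real samples differ in spread, a second simulation without any response gave each sample the spread that its limma weight implies (20 runs). In it, the share of features at an unadjusted p under 0.05 ran from 0.268% (MeJA at 3 h) to 15.1% (ACC at 3 h), so that limma's p-values were too large for MeJA and SA at 27 h and too small for SA at 3 h and for ACC. Both of these simulations drew each feature independently, whereas real features were correlated. The number of calls without a response may therefore vary more than the runs show, and their highest counts are no upper bounds. Bootstrap intervals of correlations (95%, 1000 resamplings of features) were added to tests of exchanged samples after the values were seen. They treat features as independent, which they are not.

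Alternatives written before the data were examined were: subtracting sample medians, scaling samples to equal spread, features measured in all samples, no feature filter, sample weights, a variance trend with robust estimation, no genotype term, no group terms for the genotype comparisons, the methods' t-test over the 3 genotypes with and without a 2-fold threshold, a 2-fold threshold on the mean, and leaving out each sample, genotype or hormone in turn. Fits of 1 hormone's samples alone, the interaction of hormone and time without the genotype term, and the alternatives for the counts of 2-fold features per sample, were added after seeing the data. What is called the methods' t-test took the 3 deposited values of a group, 1 per genotype. The design text gives 18 data points per time point and genotype, which were not used here. Its counts are therefore not those of the authors' own test. Figures were drawn with matplotlib 3.10.9.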

Results

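The series asked how chickpea genotypes that differ in resistance to ascochyta blight respond to 3 compounds that act in plant defence signalling. SA is a hormone of systemic acquired resistance. MeJA is a methyl ester of the wound hormone jasmonic acid, and ACC is the direct precursor of ethylene. ICC3996 is known as a resistant line, FLIP94-508C as moderately resistant and Lasseter as a susceptible cultivar. The data were 18 log2 ratios per array feature, 1 for each combination of genotype, compound and time, each the authors' mean over 3 biological replications. Between 534 and 639 of the 715 features had a value in a sample. Ratios are read as treated over untreated control, which is likely from the labels but not stated for the values. The sample medians lay between -0.32 and 0.00 on the log2 scale, so a small negative shift is part of the values as deposited.

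Fewer features were at least 2-fold from control under MeJA than under SA or ACC in each genotype at each time. SA samples had 114.5 ± 52.4 such features (SD, n = 6), ACC samples 142 ± 65.4 (SD, n = 6) and MeJA samples 19.5 ± 22.5 (SD, n = 6). Over all splits of the 12 samples, taken as independent, MeJA differed from SA (exact permutation p = 0.00649, adjusted p = 0.0227) and from ACC (exact permutation p = 0.00433, adjusted p = 0.0227). The samples pair by genotype and time, and MeJA was lower in 6 of 6 pairs with SA and in 6 of 6 with ACC. Exchanges within pairs gave an exact permutation p of 0.0312 for both, the smallest that 6 pairs allow, and an adjusted p of 0.109, which does not pass. SA and ACC were not distinguishable (exact permutation p = 0.426, adjusted p = 0.746). Within 1 time, 3 samples against 3 cannot give a p below 0.1, and both comparisons with MeJA reached that value at 3 h and at 27 h. More of these features were below control than above it in 17 of the 18 samples, and in the FLIP94-508C sample taken 27 h after MeJA 4 were above and 4 below.

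**Figure D1:**
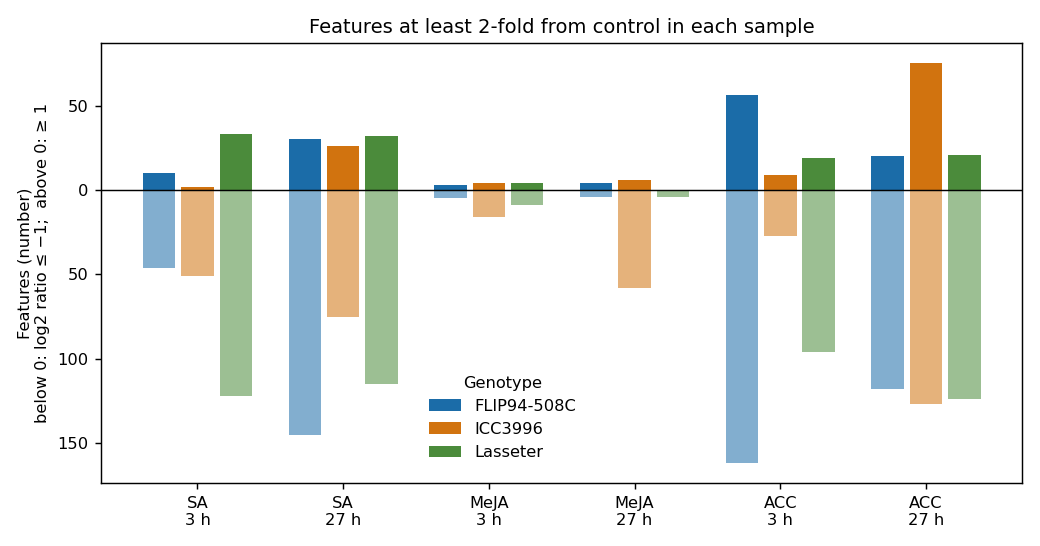
Number of array features at least 2-fold above control (bars upward, full colour) and at least 2-fold below control (bars downward, pale) in each of the 18 samples, by compound, time and genotype (colour). Each bar is 1 deposited sample with no error of its own. The MeJA samples hold 4 to 64 such features in all, and the SA and ACC samples 36 to 218.

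SA gave calls at both times, mostly of lower features. After 3 h of SA, 32 of 523 features passed the threshold, 3 higher and 29 lower. After 27 h, 76 passed, 25 higher and 51 lower, and 58 of these had a mean of at least 2-fold. The largest rises were those of U212 (log2 ratio 3.13, SE 0.51, 8.73-fold, adjusted p = 0.00361) and CA1198 (2.55, SE 0.32, 5.87-fold, adjusted p = 0.00186), both at 27 h and both higher in 3 of 3 genotypes. At 3 h the means of U212 and CA1198 were -0.03 ± 0.69 and -0.01 ± 0.49 (SD, n = 3). Among features measured in all 3 genotypes at the time in question, U033 had the largest fall, at 3 h (log2 ratio -2.83, SE 0.73, adjusted p = 0.0377), with -1.91 in FLIP94-508C, -1.19 in ICC3996 and -5.41 in Lasseter. This call was lost with equal spread (adjusted p = 0.0567), with sample weights (adjusted p = 0.0622) and in 4 of 6 fits that left out a sample or a genotype, among them those without the 3 h sample of FLIP94-508C (adjusted p = 0.0641) or of Lasseter (log2 ratio -1.37, adjusted p = 0.707). U291 fell at 27 h (log2 ratio -2.68, SE 0.37, adjusted p = 0.00187) in 3 of 3 genotypes. Without the Lasseter samples the counts were 0 at 3 h and 8 at 27 h, U212 (adjusted p = 0.0657) and U291 (adjusted p = 0.0594) no longer passed at 27 h, without FLIP94-508C they were 29 and 19, so that the order of the times turned, and a fit of the 6 SA samples alone, with 2 residual degrees of freedom, gave 0 at both times. Simulated samples with no response, unequal spreads and independent features gave at most 4 calls at 3 h and 0 at 27 h, with 6.71% and 2.28% of features at an unadjusted p under 0.05. The methods' t-test gave 0 calls at both times after adjustment, with adjusted p of 0.301 to 0.621 for the 4 named features, and 31 and 80 before it.

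Features that passed at both SA times did not all keep their direction. 9 were lower at both times, against 2.83 expected for independent lists, and 4 changed sign between 3 h and 27 h. The mean responses at the 2 times had a correlation of 0.33 across features, which are not independent replicates. Counted without a test, 6 features were at least 2-fold lower and 0 at least 2-fold higher in all 3 genotypes at 3 h. At 27 h, 16 were lower and 14 higher, where independent columns would give 1.79 and 0.0631.

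ACC gave calls mainly at 27 h. At 3 h, 4 of 523 features passed, all lower, and leaving out the ICC3996 sample raised this to 96. The count was 0 in 4 of 6 fits that left out a sample or a genotype, those without FLIP94-508C or Lasseter, and with sample weights or a variance trend. Simulated samples with no response, the spreads of the real samples and independent features gave up to 6 calls for this group and up to 4 for ACC at 27 h, with 15.1% and 9.27% of features at an unadjusted p under 0.05. At 27 h, 99 passed, 34 higher and 65 lower, and 69 had a mean of at least 2-fold. After sample medians were subtracted, the 27 h split was 47 higher and 48 lower, and after scaling to equal spread 9 features passed, 7 higher and 2 lower. ACC at 27 h had more calls than SA at 27 h (99 and 76), and the order turned with equal spread (9 and 60) and with sample weights (91 and 132). U280 (log2 ratio 2.98, SE 0.37, 7.90-fold, adjusted p = 0.000561) and LS0185 (2.34, SE 0.42, 5.05-fold, adjusted p = 0.00361) rose most at 27 h. U107 (log2 ratio -2.96, SE 0.39, adjusted p = 0.000561) and U319 (-2.67, SE 0.41, adjusted p = 0.00107) fell most. All 4 features kept their sign in 3 of 3 genotypes. With equal spread U319 (log2 ratio -1.73, adjusted p = 0.251) and LS0185 (1.68, adjusted p = 0.0971) no longer passed, nor did LS0185 without Lasseter (adjusted p = 0.0571). At 3 h LS0185 was at -3.12 in FLIP94-508C, 0.39 in ICC3996 and -1.43 in Lasseter. In all 3 genotypes, 20 features were at least 2-fold lower and 5 at least 2-fold higher at 27 h, where independent columns would give 3.34 and 0.0807. Without the ICC3996 sample at 27 h the count of 99 fell to 21, and a fit of the 6 ACC samples alone, with 2 residual degrees of freedom, gave 0 at both times. The methods' t-test gave 0 calls at 3 h and 1 at 27 h after adjustment, 0 of them among the 99, and 11 and 74 before it.

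No feature passed for MeJA at either time in limma. At an unadjusted p under 0.05 there were 10 features at 3 h and 27 at 27 h, of 523 (1.91% and 5.16%). Simulated samples with no response and the spreads of the real samples gave 0.268% and 0.746%. The methods' t-test gave 0 after adjustment and 72 and 45 before it, at 3 h more than the 31 for SA and 11 for ACC and at 27 h fewer than their 80 and 74. The largest mean responses among features with the same sign in all 3 genotypes did not pass: CA1108 was at 1.08 ± 0.76 (SD, n = 3) at 27 h (adjusted p = 0.317), and U212 at 0.83 ± 0.91 (SD, n = 3) at 3 h (adjusted p = 0.997). U344 was at -1.58 ± 2.48 (SD, n = 3) and U250 at -1.45 ± 2.08 (SD, n = 3) at 27 h, with adjusted p of 0.713 and 0.731 from limma. Both means rested on the ICC3996 sample, at -4.45 for U344 and -3.85 for U250. No feature was at least 2-fold from control in all 3 genotypes at either time. With samples scaled to equal spread 20 features passed at 3 h and 9 at 27 h, and with sample weights 4 and 6.

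**Figure D2:**
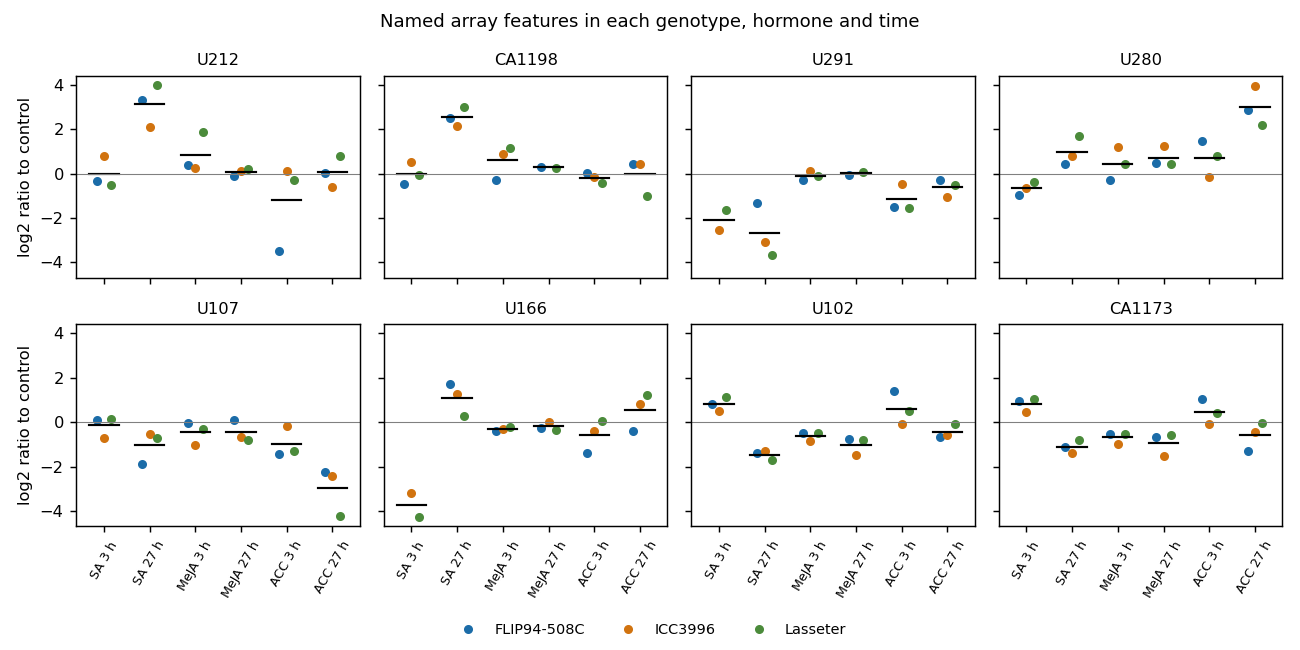
Log2 ratio to control (vertical axis) of 8 named features in each group (horizontal axis). Points are single genotypes, bars are means of the genotypes measured. U212 and CA1198 lie above 2 in all 3 genotypes 27 h after SA, and U102 and CA1173 lie above 0 at 3 h and below 0 at 27 h of SA in all 3.

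The compounds were then compared directly over both times. SA differed from ACC for 19 features, 9 higher and 10 lower under SA. U212 (difference 2.11, SE 0.51, adjusted p = 0.0331) and LS0341 (1.99, SE 0.43, adjusted p = 0.0312) were higher under SA. U160 (difference -1.97, SE 0.33, adjusted p = 0.0235) and U280 (-1.69, SE 0.37, adjusted p = 0.0312) were lower under SA. LS0341 was above control in 6 of 6 SA samples and below it in 5 of 6 ACC samples. The count of 19 became 85 without the ICC3996 sample taken 3 h after ACC, and 0 after scaling to equal spread, without Lasseter, or without any 1 of 3 samples: the Lasseter samples 3 h after ACC and 3 h after SA, and the ICC3996 sample 27 h after ACC. Of 15 fits that left out a sample or a genotype, U212 no longer passed in 12, LS0341 and U280 in 9 each and U160 in 4.

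SA differed from MeJA for 3 features, all lower under SA. The largest of these differences were those of U160 (-2.60, SE 0.33, adjusted p = 0.00171) and U291 (-2.27, SE 0.43, adjusted p = 0.0402). U160 was at -3.70 ± 0.47 (SD, n = 2) 3 h after SA and at -0.11 ± 0.17 (SD, n = 3) 3 h after MeJA. The count was 0 over features measured in all samples and without Lasseter. With equal spread 7 features passed, 4 higher and 3 lower, of which 1 was among the 3, and neither U160 (adjusted p = 0.101) nor U291 (adjusted p = 0.205) passed. U291 also no longer passed without a feature filter (adjusted p = 0.0521), with a variance trend (adjusted p = 0.0773) and in 11 of 15 fits that left out a sample or a genotype, and U160 in 1 of the 15. With sample weights 35 passed, 6 higher and 29 lower. MeJA differed from ACC for 2 features. U386 was higher under MeJA (difference 1.27, SE 0.23, adjusted p = 0.0273) and U497 lower (-1.38, SE 0.25, adjusted p = 0.0273). U497 was above control in 6 of 6 ACC samples. The count was 0 in 10 of 15 fits that left out a sample or a genotype, U386 no longer passed in 12 of the 15 and U497 in 11. Without the ICC3996 sample 3 h after ACC, 68 features passed. With sample medians subtracted 1 passed, which was lower, and with equal spread 3 were higher and 6 lower.

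The responses to SA and ACC at 27 h overlapped. Of the features called for both, 5 were higher and 12 lower under both compounds, against 1.63 and 6.34 expected for independent lists, and 2 went in opposite directions. The mean responses had a correlation of 0.50 across features. Whether both compounds were measured against the same untreated plants is not given in the sources used here. Unchanged groups against a shared control were simulated, with treated and control RNA carrying equal parts of the variance by assumption. They gave a correlation of 0.48 and 0.04 shared calls on average. The assumption itself fixes that correlation, so its closeness to 0.50 is no evidence for a shared control. Part of the excess may come from a shared control, which the simulation cannot decide. The covariance was 0.250, against 0.0564 in the simulation. Single SA and ACC samples at 27 h correlated at 0.30 to 0.46 within a genotype and at 0.27 to 0.47 between genotypes. A control shared within a genotype cannot account for the correlation between genotypes.

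**Figure D3:**
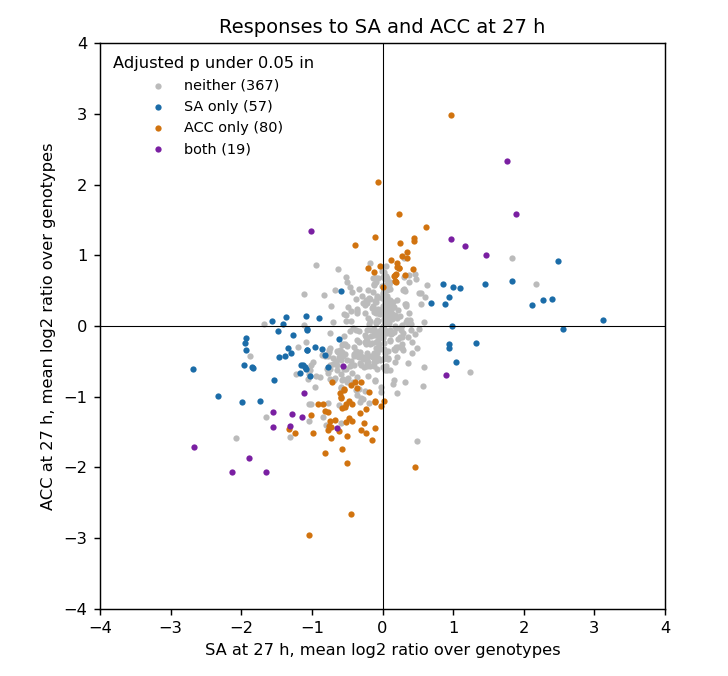
Mean log2 ratio over the 3 genotypes for each of 523 features, 27 h after SA (horizontal axis) and 27 h after ACC (vertical axis). Colour marks features with an adjusted p under 0.05 for SA (57), ACC (80), both (19) or neither (367), and most of the 19 lie in the lower left and upper right quadrants.

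The change from 3 h to 27 h was tested within each compound. Under SA, 11 features differed, 9 higher and 2 lower at 27 h, and over features measured in all samples 2 passed, 0 higher and 2 lower. U166 was higher at 27 h by 4.96 (SE 0.54, adjusted p = 0.000355), a difference of fitted means (-3.87 and 1.09) that allows for the missing FLIP94-508C value at 3 h. The measured means were -3.74 ± 0.76 (SD, n = 2) and 1.09 ± 0.73 (SD, n = 3). LS0159 was higher by 4.43 (SE 0.80, adjusted p = 0.0125), from -2.32 ± 2.25 to 2.11 ± 0.57 (SD, n = 3). U102 (difference -2.28, SE 0.30, adjusted p = 0.000932) and CA1173 (-1.93, SE 0.32, adjusted p = 0.00602) were lower at 27 h. Both were above control at 3 h and below it at 27 h in 3 of 3 genotypes. Under ACC, LS0185 alone passed (difference 3.72, SE 0.60, adjusted p = 0.0153), and under MeJA no feature passed in limma, with 1 at an unadjusted p under 0.05. The count under ACC was 0, and LS0185 did not pass, in 5 of 9 fits that left out a sample or a genotype and with equal spread (adjusted p = 0.520). It was 19 without the FLIP94-508C sample at 3 h and 11 without the ICC3996 one. Under SA the count was 0 without ICC3996 and in the fit of SA samples alone, and of 9 fits that left out a sample or a genotype LS0159 no longer passed in 5, U102 and CA1173 in 2 each and U166 in 1.

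Averaged over compounds, 3 features differed between the times: U166 (2.07, SE 0.28, adjusted p = 0.00224) was higher at 27 h, and U102 (-1.24, SE 0.17, adjusted p = 0.00224) and CA1173 (-1.08, SE 0.18, adjusted p = 0.00853) were lower. None passed without Lasseter, and 27 did without the FLIP94-508C sample 3 h after ACC. Without FLIP94-508C 1 feature passed, and neither U102 nor CA1173 did (both adjusted p = 0.0640), and without ICC3996 neither U166 nor CA1173 passed (both adjusted p = 0.0747). After scaling to equal spread 2 passed, 1 in each direction, and CA1173 did not (adjusted p = 0.0901), and with sample weights 39, 20 higher and 19 lower. The time change of U166 also differed between compounds (adjusted p = 0.0254 in limma's F test), the only call of that interaction among 523 features. In simulated data with equal spread that F test recovered only 24% of 2-fold changes, so 1 call does not show that such differences were rare. U166 was at -0.32 ± 0.09 and -0.20 ± 0.19 (SD, n = 3) at the 2 MeJA times and at -0.58 ± 0.74 and 0.54 ± 0.84 (SD, n = 3) at the ACC times. This interaction had 48 features at an unadjusted p under 0.05, and its call was lost with equal spread. Of 21 fits that left out a sample or a genotype, 11 gave 0 calls, among them each of the 6 without a MeJA sample, and without FLIP94-508C or without ICC3996 the 1 call was another feature. The count was 7 without the ICC3996 sample 3 h after ACC and 6 with sample weights.

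The genotypes did not differ for any feature in limma when the 6 samples of 1 were compared with those of another. At an unadjusted p under 0.05 there were 13 features for ICC3996 against Lasseter, 36 for FLIP94-508C against Lasseter and 6 for ICC3996 against FLIP94-508C, of 523. The counts of 2-fold features per sample were 100.5 ± 89.3 in FLIP94-508C, 79.3 ± 66.1 in ICC3996 and 96.5 ± 69.6 in Lasseter (SD, n = 6), and no pair differed (exact permutation p from 0.636 to 0.939, adjusted p from 0.778 to 0.939). The interaction of compound and genotype had 0 calls among 515 features in limma and 21 at an unadjusted p under 0.05. In that model the 2 times served as the repeats, so time changes that differed between compounds or genotypes added to its residual. Its 0 calls therefore do not show that the genotypes responded alike. The profiles of the 3 genotypes were most alike 27 h after SA, with a mean pairwise correlation of 0.60 across features, and 27 h after ACC, with 0.53. At 3 h the mean was 0.36 for SA, 0.19 for ACC and 0.17 for MeJA, and at 27 h it was 0.28 for MeJA. The sample 3 h after ACC had 218 features at least 2-fold from control in FLIP94-508C, 115 in Lasseter and 36 in ICC3996.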

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

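Tests of smaller MeJA ratios, of exchanged ACC samples and of deviations shared within FLIP94-508C were chosen only after the result was seen, and the simulation of unequal spread likewise. With 17 groups searched for a sample far from the others, chance marks about 1 in 20 groups.

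Among the 6 MeJA samples, ICC3996 at 27 h stood far from the others, with 64 features at least 2-fold from control against 4 to 20. The normalisation control NORMCON3 was at -0.71 (log2) in ICC3996 3 h after ACC, far from the other ACC samples, which lay between -2.24 and -2.65. NORMCON3, which no comparison used, had a mean of -1.19 ± 0.99 (SD, n = 5) under SA and -2.05 ± 0.77 (SD, n = 5) under ACC, outside the range of the controls NORMCON2 and NORMCON4 over all samples (-0.28 to 0.22). Under MeJA it was at -0.16 ± 0.25 (SD, n = 6).

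Several features responded differently at the 2 times in limma. Under SA the difference of 27 h and 3 h was 4.96 for U166 (adjusted p = 0.000355), 4.43 for LS0159 (adjusted p = 0.0125), -2.28 for U102 (adjusted p = 0.000932) and -1.93 for CA1173 (adjusted p = 0.00602). Under ACC it was 3.72 for LS0185 (adjusted p = 0.0153). Averaged over compounds it was 2.07 for U166, -1.24 for U102 and -1.08 for CA1173. The time change of U166 differed between compounds with an adjusted p of 0.0254. U280 was below control in 3 of 3 genotypes 3 h after SA and above it in 3 of 3 at 27 h, a difference of 1.64 that did not pass the threshold.

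Labels were exchanged to see whether other groupings gave as many calls. Exchanges stayed within blocks of samples, except for time within 1 compound, where all splits of its 6 samples were taken. For SA against MeJA, 1 of 32 groupings, the real one, gave 3 calls and the highest other gave 1. That share is under 5%, but it is the smallest that 32 groupings allow. It was not adjusted for the number of comparisons tried, so chance is not excluded. For SA against ACC, 3 of 32 gave at least the real 19, and for MeJA against ACC 2 of 32 gave at least the real 2, so chance cannot be excluded for either. For time over all compounds 5 of 100 groupings gave at least the real 3 calls (highest other 5), and for the interaction of compound and time 14 of 100 gave at least 1 (highest other 7), so chance cannot be excluded there. Within 1 compound the 10 splits of 6 samples, which ignored the pairing of the times by genotype, are too few for a share under 0.05. The real and the highest other count were 11 and 1 under SA, where 1 of 10 splits reached the real count, 0 and 0 under MeJA (10 of 10), and 1 and 63 under ACC (3 of 10). For the 3 genotype comparisons the real count was 0, so all 32 of 32 groupings reached it, and the highest other was at most 1. Groupings with many more calls than the real one point to a structure of the samples. The 63 came from setting both FLIP94-508C samples and ICC3996 at 27 h against the other 3 ACC samples. The highest counts of SA against ACC (89) and of MeJA against ACC (26) came from exchanging 1 pair of labels, those of ICC3996 at 3 h.

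The first pattern weighed is that most calls were negative: 145 of 207 (70.0%) over SA at 3 h, SA at 27 h and ACC at 27 h, or 70.0% positive if the ratio, whose direction is only likely, were control over treated. Spots near background that were omitted in some samples do not account for it as the whole cause, since features measured in all samples still gave 63.3%, and at least 66.7% with any genotype left out. An offset of whole samples from 0 stays open in part, because subtracting sample medians brought the share to 59.7%, neither at 50% or less nor above 60% (63.0% to 68.5% with a genotype left out). Both changes together gave 56.6% (82 of 145), and 61.6% to 70.0% with a genotype left out, so whether the 2 act jointly stays open. Single values were also lopsided, with a lowest of -11.3 (ICC3996 27 h after MeJA) and a highest of 4.07 (FLIP94-508C 27 h after ACC). Dim spots that were not omitted were not tested as a source of this. A real excess of changes in 1 direction is a biological explanation that also stays open, and it was not tested further.

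The second pattern is that no feature passed for MeJA. Smaller MeJA ratios may account for it, since each comparison of 2-fold features per sample had an exact permutation p of 0.00649 or less over free splits, and of 0.0312, the smallest possible, with exchanges within pairs of 1 genotype and time (adjusted p = 0.109). This measure was chosen after the data were seen and cannot weigh smaller ratios against a shared spread. A spread shared with the more variable SA and ACC samples also stays open: sample weights gave 10 calls over both times, between the bounds set beforehand, and a fit of the MeJA samples alone decides nothing, because such fits have 2 residual degrees of freedom and gave 0 for SA and ACC as well, while the methods' t-test, which shares no spread, gave 72 features at 3 h before adjustment, more than for SA (31) or ACC (11), and 0 after it. Simulated samples without a response had 0.268% and 0.746% of features at an unadjusted p under 0.05 for MeJA, so the shared spread made that test strict, but 6.71% for SA at 3 h and 15.1% and 9.27% for ACC at 3 h and 27 h, so that the p-values of those groups may be too small. Whether the plants responded less or received an effectively lower dose was not tested, and doses are not given in the sources used here.

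The third pattern is that the ACC 3 h samples of the 3 genotypes did not resemble each other, with pairwise correlations of -0.04 to 0.37 across features. FLIP94-508C at 3 h resembled ICC3996 at 27 h (r = 0.62) more than at 3 h (-0.04). Against Lasseter the order was reversed (0.20 and 0.37). A swap of its 2 ACC samples needs a difference of mean r above 0 for the 27 h sample. That difference was -0.45 (95% bootstrap interval over features -0.54 to -0.35), which argues against a swap. Against Lasseter alone it was -0.12, and the larger part came from ICC3996, whose 3 h sample is itself in doubt. The FLIP94-508C 3 h sample went the other way. Its mean r was 0.41 with the ACC 27 h samples of the other genotypes and 0.17 with their 3 h samples. A swap is therefore not excluded. Deviations shared by FLIP94-508C at both times also stay open. Its 3 h sample had an r of 0.58 with its own 27 h sample, against 0.62 with ICC3996 at 27 h. The difference of r was -0.036 (interval -0.083 to 0.011), where at least 0.1 was required. Against Lasseter at 27 h r was only 0.20, so the outcome rests on the genotype taken for comparison. A swap of the ICC3996 samples taken 3 h after ACC and 3 h after SA may explain the odd ICC3996 sample and stays open: both samples correlated more with the exchanged group, by 0.13 and 0.053, both intervals include 0 (-0.013 to 0.292 and -0.051 to 0.169), and the difference of SA and ACC at 3 h in ICC3996 correlated with that in FLIP94-508C at -0.43 (-0.52 to -0.33) but with that in Lasseter at 0.21 (0.089 to 0.316), where a swap would put both below 0 and correct labels both above it. Single features also go both ways, and they were not tested as a set. NORMCON3 in the ICC3996 ACC sample (-0.71, singled out before this reading, with no value in the ICC3996 SA sample) lay nearer to SA at 3 h in FLIP94-508C (-0.64) and Lasseter (-0.27). U160 and U166, which were named with these samples in the fit, went as their labels say. They were at -4.04 and -3.20 in ICC3996 SA (Lasseter SA -3.37 and -4.28) and at 0.04 and -0.39 in ICC3996 ACC. U250 was at -1.26 in ICC3996 SA and cannot tell, since the other SA values (-1.11 and -1.21) lay between the other ACC values (-2.81 and -0.96). U280 in ICC3996 was at -0.63 under SA and -0.15 under ACC, both nearer to the other SA values (-0.95 and -0.40) than to the other ACC values (1.48 and 0.79). LS0185 in ICC3996 ACC (0.39) lay near SA (0.50 and 0.52). U497 in ICC3996 SA (0.53) lay nearer to the other ACC values (1.69 and 1.05) than to the other SA values (-0.57 and -0.52). A difference of the genotypes in the speed of the response, which was not tested, also remains.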

How the results depend on the processing

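Fits of 1 compound's samples alone, the interaction of compound and time without the genotype term, counts of 2-fold features per sample under other settings, their exchanges within pairs and 2-fold counts with a genotype left out were chosen only after the result was seen. Besides leaving out samples, 194 alternative values of counts and differences were computed, of which 130 lay within 1.5 times the reported count or on the same side of the threshold. Counts of 0 that stayed at 0, as in most settings for MeJA and the genotype comparisons, are among the 130. The 130 therefore overstates how stable the comparisons with calls were. For the other 64 the cause was not tested, except that fewer features or samples enter some fits by construction. Subtracting sample medians gave 7 calls for ACC at 3 h and 1 for MeJA against ACC. Scaling to equal spread gave 11 for SA at 3 h, 20 and 9 for MeJA at 3 h and 27 h, 9 for ACC at 27 h, 7 for SA against MeJA, 9 for MeJA against ACC, 1 for the interaction of compound and genotype, and 0 for time under ACC, for SA against ACC and for the interaction of compound and time. Features measured in all 18 samples gave 42 for SA at 27 h, 14 for ACC at 3 h, 2 for time under SA (0 higher, 2 lower), and 0 for SA against MeJA and for the interaction of compound and time. Without a feature filter there were 124 for SA at 27 h, 15 for ACC at 3 h, 20 for time under SA, 1 for SA against MeJA and 6 for MeJA against ACC. Sample weights gave 20 and 132 for SA at 3 h and 27 h, 4 and 6 for MeJA, 0 for ACC at 3 h, 10 for time under ACC, 39 for time over all compounds, 35 for SA against MeJA, 16 for MeJA against ACC and 6 for the interaction of compound and time. A variance trend with robust estimation gave 0 for ACC at 3 h and 1 for SA against MeJA. Without the genotype term, that is with no replicate block, the time comparisons gave 18 under SA, 5 under ACC and 5 over all compounds, and MeJA against ACC gave 12. The block moved no other count of responses or of compound comparisons by over 1.5 times, and the interaction of compound and time had 1 call without it, U166 again. The methods' t-test, adjusted, gave 0 for SA at both times and for ACC at 3 h and 1 for ACC at 27 h, and 0 in all 4 groups with a 2-fold threshold. At an unadjusted p under 0.05 this t-test gave 31, 80, 11 and 74. Fits of 1 compound's samples alone gave 0 for SA and ACC at both times and for time under SA and under ACC. Features beyond the threshold in all 3 genotypes numbered 18, 87, 1, 9, 16 and 82 at 1.5-fold, for SA, MeJA and ACC at 3 h and 27 h in turn, and 39, 103, 2, 2, 55 and 121 at 2-fold in at least 2 of 3 genotypes.

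Leaving out 1 sample or 1 genotype gave 0 (without Lasseter) to 38 calls for SA at 3 h, 8 (without Lasseter) to 54 for SA at 27 h, 0 to 96 (without ICC3996 at that time) for ACC at 3 h, 21 (without ICC3996 at that time) to 85 for ACC at 27 h, and 0 to 0 for MeJA at both times. It gave 0 (without ICC3996) to 26 (without FLIP94-508C at 3 h) for time under SA, 0 to 0 under MeJA, 0 to 19 (without FLIP94-508C at 3 h) under ACC and 0 (without Lasseter) to 27 (without FLIP94-508C 3 h after ACC) over all compounds. For SA against MeJA it gave 0 (without Lasseter) to 12 (without ICC3996 3 h after SA), for SA against ACC 0 to 85 and for MeJA against ACC 0 to 68, both highest without ICC3996 3 h after ACC. The interaction of compound and time gave 0 to 7, that of compound and genotype 0 to 1, and the genotype comparisons 0 to 0. Features 2-fold in both remaining genotypes numbered 11 to 29 and 47 to 73 for SA, 0 to 3 and 0 to 1 for MeJA, and 7 to 51 and 45 to 88 for ACC, at 3 h and 27 h. The difference of 2-fold features per sample ran from 82.9 to 107.3 for SA minus MeJA (exact permutation p at most 0.013), from -144.1 to -107.7 for MeJA minus ACC (exact permutation p at most 0.00866) and from -49.1 to -12.7 for SA minus ACC. Of 457 alternative values of named features that passed, 323 still passed, 134 no longer did and 0 changed sign. Of 60 for MeJA features that did not pass, 3 passed, those of U212 and CA1108 with equal spread and of CA1108 with sample weights. The named features were chosen as the largest in these same samples, and several settings change the test but not the estimate. A feature without a value in a setting was not counted there. That 0 of the 457 changed sign therefore says little. Tests of gene lists, with an estimated correlation, fry or 1 value per description, were not run, because no feature could be matched to a gene. Signal over background was not used here, so the effect of dim spots on single ratios is open.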

Other observations

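All tests in this part were chosen only after the result was seen.

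The called features came from all 3 kinds of identifier. At 27 h of SA, 13 of 100 tested CA features passed, 11 of 88 LS features and 52 of 335 U features (Fisher's exact p = 0.750, adjusted p = 0.750). At 27 h of ACC they numbered 19, 11 and 69 (Fisher's exact p = 0.229, adjusted p = 0.344), and at 3 h of SA 7, 1 and 24 (Fisher's exact p = 0.0686, adjusted p = 0.206). The share of features that could be tested did differ between the kinds: 85.5% of 117 CA features, 56.4% of 156 LS features and 75.8% of 442 U features (Fisher's exact p = 1.19e-07). In all, 173 of 523 features were called in at least 1 response, 95 for SA at either time and 100 for ACC at either time.

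Some pairs of features were highly correlated over the samples. Among the 444 features measured in all 18 samples, 49 pairs had a correlation of at least 0.95 over the samples, where 100 shufflings of the samples within each feature gave 1 pair at most. These pairs involved 56 features in 16 linked groups, the largest of 8. Of the 123 called features measured in all samples, 8 belonged to such a pair. Shuffling each feature alone removes every response and every extreme sample that features share, so an excess over it was likely beforehand. A correlation this high can also rest on 1 extreme sample, which was not checked. Whether linked features represent 1 gene was not tested, since no gene names were used.

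Profiles of different compounds correlated across features, and 1 hypothesis is that all compounds of a genotype and time were set against the same untreated plants. Then the correlation between compounds at 1 time would be higher within a genotype than between genotypes. The mean was 0.216 over 18 pairs within a genotype and 0.212 over 36 pairs between genotypes (exact one-sided permutation p = 0.410 over 1296 relabellings). The data do not bear the hypothesis out and cannot exclude it, because a control shared in this way may add little to ratios with large responses.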
